A study of Rattus norvegicus with 18 samples.

How the data were processed

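The series holds RNA sequencing of rat renal parenchyma after ligation of the left ureter. Per the labels' protocols, RNA was extracted with RNAiso Plus, poly(A) RNA was captured on oligo-dT beads and first-strand cDNA was made with random hexamers and M-MuLV reverse transcriptase. Per the submitters' processing notes, reads were cleaned with fastp 0.19.7 and aligned with HISAT2 2.0.4. The counting tool, its use of strand, the annotation release and the genome build are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and coordinates are those of the deposited table with no build named. The deposited table gives a read count per gene and library, per the file headers. It also gives FPKM per gene and library, per the file headers, which do not say how FPKM was made. Recomputing the deposited FPKM showed them to equal the count divided by a single length per gene and by the column total, scaled by a constant (checked on 12596 genes with at least 50 counts, largest ratio of implied lengths 1.00002).

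Libraries were assigned to 1, 3, 7 or 14 days by their labels alone. The design also names a sham group and a metabolite measurement; the sham group was not analysed here and the metabolites were not used here. Every library carries the same batch label. The labels speak of animals divided into groups but do not tie each library to a separate animal, so p-values measure the spread between libraries, which may in part be technical. Column totals were 5488540 to 12049915 counts, and CPM are counts divided by the total of the library and scaled by a constant. The table has 30957 genes, of which 22014 had a count in at least 1 library. No library was left out of the reported tests.

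The plan fixed before the data were examined named edgeR for deposited counts and limma on log2(FPKM+1) if FPKM alone were present; since counts are present, edgeR was used and the FPKM fit became an alternative. The groups, the 4 comparisons, the gene lists, the rule for named genes and most alternatives were also fixed before the data were examined. Genes were filtered with filterByExpr (min.count 10, min.total.count 15), which left 14511. Counts were scaled by TMM factors and fitted with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood, all 18 libraries in a single model with 1 coefficient per group. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Standard errors were taken as the log2 fold change divided by the square root of the F statistic. The comparison of 7 with 1 day was added after the data were seen.

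The gene lists numbered 42, of which 40 had at least 5 tested members. Of 1251 members 1223 were found in the table, 1217 by symbol and 6 by an older symbol, with names of the GRCr8 RefSeq table used for older symbols alone. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, Benjamini-Hochberg adjusted over lists within a comparison. Members called are counted over all tested genes and, separately, when adjusted over the list alone. The score of a list in a library is the mean over tested members of log2(FPKM+1) minus the gene's mean over the 18 libraries.

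The rule for named genes took, per comparison, the 10 called genes with the largest positive and the 10 with the largest negative log2 fold changes that had an FPKM of at least 5 in the higher group and no overlap between libraries. Per list it took up to 4 called members in the majority direction and 2 in the other (3 each at equal numbers), or the 2 with the smallest p where none was called, and it added a fixed set of marker genes. The text names part of these. Where a group had no count in any library, the gene is not named in that comparison.

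On simulated counts with 200 changed genes, the test recovered 46.9% of 2-fold and 86% of 4-fold changes for 3 versus 1 day, 59.6% and 88% for 7 versus 3 days, 55.6% and 86% for 7 versus 1 day, 40% and 83% for 14 versus 7 days, and 42.4% and 80.8% for 14 versus 1 day. Between 4.1% and 6.4% of the calls were false. The cell cycle list raised 1.5-fold was recovered in each simulation. Simulated genes varied independently of each other, around the gene's mean over all libraries and with the same dispersion in every group. These rates therefore need not hold for the libraries labelled 14 days, which varied more, or for lists whose genes move together.

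Alternatives covered DESeq2 1.42.0, RLE factors, other filters and pseudocounts, TPM, upper-quartile, median and quantile scaling of FPKM, fits on the 2 groups alone, limma array weights, robust variance estimates, the replicate number as a block, a size threshold of 1 on the log2 scale and each library left out in turn. Alternatives added after the data were seen left out the libraries labelled 14 days, replicate 5 of day 1 or both, kept only replicate 2 of those labelled 14 days, left out mitochondrial genes, or used the mean of the urothelium, adipocyte and principal cell scores as a covariate. Tables and figures were made with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.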

Results

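Renal parenchyma was profiled by poly(A) RNA sequencing in a rat time course of unilateral ureteral obstruction, in which the left ureter was tied and the kidney was taken after a set number of days. The 18 libraries comprised 5 at 1 day, 5 at 3 days, 5 at 7 days and 3 labelled 14 days. The study design also names a sham group, which was not analysed here, so every comparison is between labelled durations of obstruction and none includes a library labelled as unobstructed. Library totals ran from 5488540 to 12049915 counts, 22014 genes had a count in at least 1 library and 14511 were tested. Transcripts of the mitochondrial genome made up 9.85 ± 2.24% of counts at 1 day, 9.31 ± 2.39% at 3 days, 8.05 ± 0.91% at 7 days (mean ± SD, n = 5 each) and 21.93 ± 6.73% in the libraries labelled 14 days (n = 3). Among the 4 durations 6929 genes differed (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted; 8093 at an unadjusted p under 0.05), and 4816 differed among the first 3 durations when the libraries labelled 14 days were left out. The first principal component, with 40.5% of the variance, set apart replicates 1 and 3 labelled 14 days (scores 125.9 and 143.9) and replicate 5 of day 1 (54.5) from all others (−30.8 to −12.6). On the second, with 18.6%, replicate 2 labelled 14 days stood apart at 112.1, against −49.9 to 21.7 in all others.

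The tubular injury marker Havcr1, which encodes the shed receptor KIM-1, was abundant in every library of the first 3 durations, at 801 ± 160 FPKM at 1 day, 473 ± 160 at 3 days and 381 ± 91.6 at 7 days (mean ± SD, n = 5 each). Spp1, encoding osteopontin, was at 6639 ± 942, 10210 ± 3264 and 10960 ± 1611 FPKM in the same groups. In the libraries labelled 14 days both were close to absent by comparison, at 3.10 ± 3.82 and 125 ± 117 FPKM (n = 3). In the deposited annotation Havcr1 (ENSRNOG00000007243) lies on chromosome 10 from 31813814 to 31848379 and Spp1 (ENSRNOG00000043451) on chromosome 14 from 6673686 to 6679901.

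**Figure D1:**
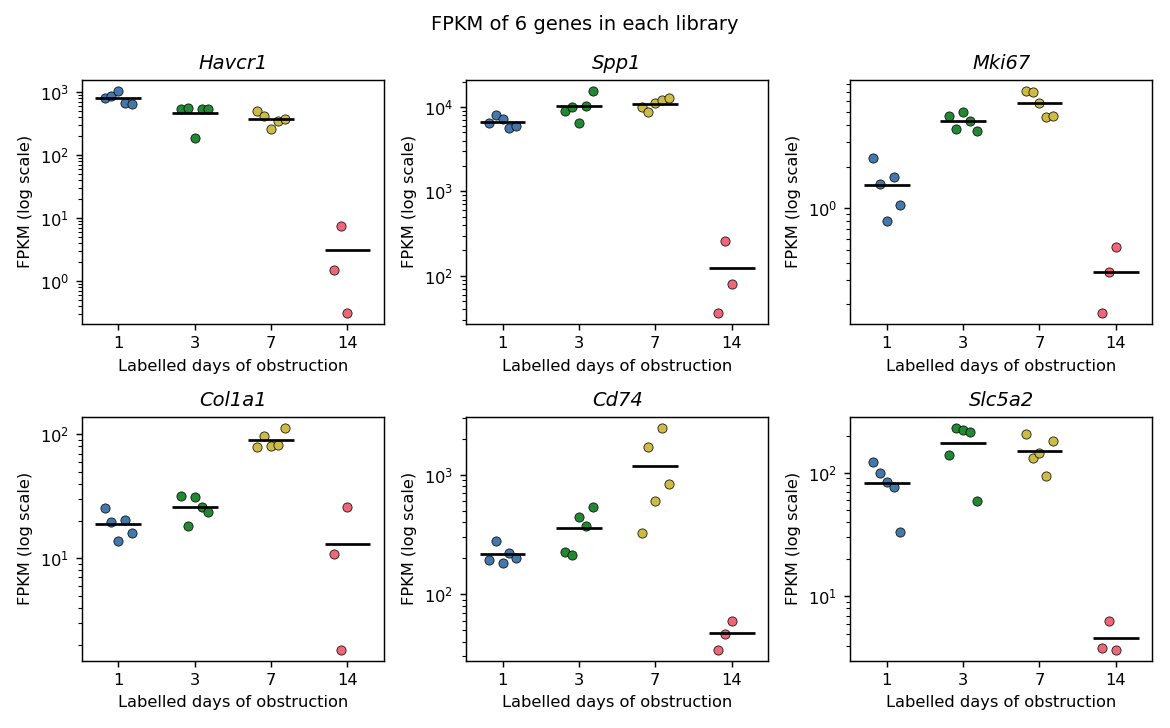
FPKM of 6 genes in each of the 18 libraries against the labelled days of obstruction, on a logarithmic axis. Points are libraries and bars are group means (n = 5, 5, 5 and 3).

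From 1 to 3 days of obstruction, genes of cell division rose. Of the 46 measured members of the cell cycle list 23 rose and 0 fell (31 rose when adjusted over the list alone), with a median log2 fold change of 1.17. The list test gave an adjusted p = 4.7e-48 (camera; adjusted p = 0.0315 with an estimated correlation). Plk1, a kinase of mitotic entry, went from 1.4 ± 0.427 to 5.05 ± 0.993 FPKM (n = 5 each), a log2 fold change of 1.84 ± 0.24 (SE; edgeR adjusted p = 0.00131). Cenpf, a kinetochore protein, rose by 2.21 ± 0.32 (adjusted p = 0.00263). Top2a, the topoisomerase that untangles replicated DNA, rose by 1.79 ± 0.31 (adjusted p = 0.00734) and the proliferation marker Mki67 by 1.53 ± 0.26 (adjusted p = 0.00689). Mki67 was still low in FPKM, at 1.47 ± 0.576 and then 4.25 ± 0.562. Plk1 (ENSRNOG00000018815) lies on chromosome 1 from 192115966 to 192125989 and Cenpf (ENSRNOG00000003388) on chromosome 13 from 108132499 to 108178609. Without the libraries labelled 14 days the cell cycle list kept its call (adjusted p = 1.5e-37; adjusted p = 0.261 with an estimated correlation).

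Interferon-response genes were lower at 3 days. The median of 34 members was −0.76 and the mean −1.21 (camera, adjusted p = 3.5e-07; adjusted p = 0.972 with an estimated correlation). Of the members 1 fell and 0 rose (11 fell when adjusted over the list alone). Rsad2, the antiviral protein viperin, went from 27.3 ± 25.6 to 3.34 ± 1.44 FPKM, a log2 fold change of −3.03 ± 0.57 (edgeR, adjusted p = 0.0123). Much of the day 1 level came from replicate 5, whose interferon score was 1.75 against −0.32 to 0.1 in the other 4 libraries, and without that library the median was −0.32 (adjusted p = 0.00386).

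Of the leukocyte lists 3 moved up modestly from 1 to 3 days. The list of MHC class II presentation had a median of 0.83 over 14 members with 0 called (5 rose when adjusted over the list alone; camera, adjusted p = 8.4e-05). Monocyte and macrophage genes had a median of 0.5 over 34 members with 1 called (2 over the list alone; adjusted p = 0.00035), and T and NK cell genes 0.63 over 31 members with 1 called (1 over the list alone; adjusted p = 0.000927). Neutrophil (10 members, median −0.09, adjusted p = 0.995), dendritic cell (11 members, median 0, adjusted p = 0.995) and B and plasma cell genes (17 members, median 0.44, adjusted p = 0.0551) were not called. None of the 3 called lists held with an estimated correlation (adjusted p = 0.972 for each). The members that rose were Clec10a, a lectin of macrophages and dendritic cells, by 2.45 ± 0.57 (edgeR, adjusted p = 0.0381, 1.77 ± 1.03 to 9.89 ± 5.01 FPKM), and the coreceptor gene Cd4 of the T and NK cell list, by 1.25 ± 0.3 (adjusted p = 0.0398). Cd3e of the same list was not called (1.22 ± 0.44, adjusted p = 0.154). The class II gene RT1-Da (1.72 ± 0.49, adjusted p = 0.0776) and the class II transactivator Ciita (1.61 ± 0.52, adjusted p = 0.117) were not called. With the libraries labelled 14 days left out RT1-Da was called (1.71, adjusted p = 0.046) and Ciita was not (1.59, adjusted p = 0.0607). Reads shared between near-identical RT1 genes leave the levels of these genes uncertain here and in the comparisons that follow. Clec10a (ENSRNOG00000018715) lies on chromosome 10 from 56764927 to 56769457.

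Proximal tubule genes had a median of 0.73 over 39 members with 0 called (camera, adjusted p = 0.00035; adjusted p = 0.972 with an estimated correlation). Replicate 5 of day 1 had a score of −1.01 for this list against −0.19 to 0.36 in the other 4 libraries of its group, and without it the list was still called, with a median of 0.55. Gatm, an enzyme of creatine synthesis (1.94 ± 0.55, edgeR adjusted p = 0.0762), and the brush-border dipeptidase Dpep1 (1.44 ± 0.38, adjusted p = 0.0595) are examples, and both were called without the libraries labelled 14 days (1.94, adjusted p = 0.0261, and 1.42, adjusted p = 0.0356). Beside these, Krt7, a keratin of collecting duct and urothelium, rose by 1.14 ± 0.28 (adjusted p = 0.0451). The urothelium list was not called (11 members, median −0.32, although the test pointed up, adjusted p = 0.793), and neither were adipocyte genes (median −0.74, adjusted p = 0.826) or mitochondrially encoded genes (median −0.1, adjusted p = 0.716).

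In the glutathione and antioxidant list 3 of 42 members fell from 1 to 3 days and 0 rose (5 fell when adjusted over the list alone), although the list as a whole was not called (camera, adjusted p = 0.664). Gstm1, a glutathione transferase whose close paralogues may share its reads, went from 330 ± 133 to 73.0 ± 36.4 FPKM (−2.17 ± 0.5, edgeR adjusted p = 0.0368). Hmox1, the haem-degrading enzyme, went from 41.9 ± 11.0 to 14.3 ± 5.31 FPKM (−1.59 ± 0.36, adjusted p = 0.0323). The amino acid catabolism list was not called (57 members, 2 fell, median 0.2, camera adjusted p = 0.338), and neither was the tryptophan list (25 members, 1 fell, median 0.44, adjusted p = 0.181). Asl, of the urea cycle, went from 102 ± 19.3 to 51.0 ± 9.52 FPKM (−1.01 ± 0.18, adjusted p = 0.00832). Got1, an aspartate aminotransferase, changed by −1.05 ± 0.23 (adjusted p = 0.0294). Trib3, an ATF4 target of the amino acid response, changed by −1.86 ± 0.4 (adjusted p = 0.0261). Tph1, the serotonin-synthesis hydroxylase, changed by −2.17 ± 0.35 (adjusted p = 0.00532) and the death receptor Fas by −1.02 ± 0.2 (adjusted p = 0.0170).

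In all, 330 genes differed between 3 and 1 days, 168 higher and 162 lower (edgeR, Benjamini-Hochberg; 2624 at an unadjusted p under 0.05). Without the libraries labelled 14 days, a setting added after the data were seen, the count was 1463 (738 higher, 725 lower, 324 of them shared). The largest rises among well-expressed genes included Acsm5, a medium-chain acyl-CoA synthetase (2.84 ± 0.61, adjusted p = 0.0260), and Cpz, a carboxypeptidase that binds Wnt proteins (1.99 ± 0.26, adjusted p = 0.00131; 2.61 ± 0.714 to 10.6 ± 4.06 FPKM). Fbln5, an organiser of elastic fibres, rose too (1.54 ± 0.24, adjusted p = 0.00475; 14.9 ± 4.06 to 43.7 ± 9.44 FPKM). The falls, beside Rsad2, included Sdcbp2, a PDZ adaptor (−4.33 ± 0.64, adjusted p = 0.00277; 14.5 ± 6.25 to 0.725 ± 0.567 FPKM), the haem carrier Hpx (−2.77 ± 0.42, adjusted p = 0.0034) and the muscle-type elongation factor Eef1a2 (−2.68 ± 0.38, adjusted p = 0.00216). Sdcbp2 (ENSRNOG00000009528) lies on chromosome 3 from 147073160 to 147101911. Havcr1 (−0.79 ± 0.53, adjusted p = 0.449), Spp1 (0.6 ± 0.41, adjusted p = 0.473), Col1a1 (0.44 ± 0.38, adjusted p = 0.568) and the monocyte attractant Ccl2 (−2.04 ± 0.62, adjusted p = 0.0942) were not called. With the libraries labelled 14 days left out Ccl2 was called (−2.05, adjusted p = 0.00242), and Havcr1 (adjusted p = 0.0523), Spp1 (adjusted p = 0.0696) and Col1a1 (adjusted p = 0.136) were not. The 5 libraries of each group separated fully in 1167 genes (8% of those tested, 0.794% by chance). On deposited FPKM the split was 144 higher and 74 lower with log2(FPKM+1) and 125 and 41 with TPM.

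The 3 versus 1 day count moved with single libraries. Leaving out 1 library gave 143, 192, 115 and 120 genes without replicates 1 to 4 of day 1, and 172, 181, 122, 120 and 190 without replicates 1 to 5 of day 3. It gave 1159 and 517 without replicates 2 and 3 labelled 14 days. Clec10a, Cd4, Krt7, Acsm5, Gstm1, Hmox1, Trib3, Got1 and Fas each lost the call in at least 1 of these refits. They did so with fold changes that moved less than 1.5 times and adjusted p no higher than 0.124 (Krt7 without replicate 3 of day 1). A further 6 lists, of loop, fibroblast, Wnt, fatty acid oxidation, oxidative phosphorylation and cholesterol genes, had medians between −0.18 and 0.59 and adjusted p from 0.0102 to 0.0403 (camera; adjusted p = 0.972 for each with an estimated correlation). The call was lost for loop genes without replicates 3 or 4 of day 1 or 1 or 3 of day 3 (adjusted p up to 0.0997), and for fibroblast genes without 2, 3 or 4 of day 1 or 1 or 3 of day 3 (up to 0.145). It was lost for Wnt genes without 2 or 4 of day 1 or 1 of day 3 (up to 0.0997), and for fatty acid oxidation genes without 5 of day 1 or 3 of day 3 (up to 0.123). For oxidative phosphorylation it went without 3 or 5 of day 1 or 2 or 3 of day 3 (up to 0.362), and for cholesterol genes without 5 of day 1 or 1, 3 or 5 of day 3 (up to 0.162).

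Between 3 and 7 days the kidney gained transcripts of scar matrix. In the list of collagens and matrix proteins 3 of 36 members rose and 0 fell (26 rose when adjusted over the list alone), median 1.01 (camera, adjusted p = 4.6e-17; adjusted p = 0.259 with an estimated correlation). Col1a1, the main chain of type I collagen, went from 26.1 ± 5.68 to 90.5 ± 14.5 FPKM (n = 5 each; 1.72 ± 0.38, edgeR adjusted p = 0.0472). Sparc, a matricellular collagen binder, went from 189 ± 22.5 to 600 ± 77.8 FPKM (1.6 ± 0.27, adjusted p = 0.0155), and Thbs2, an antiangiogenic thrombospondin, from 0.740 ± 0.36 to 4.81 ± 2.59 FPKM (2.61 ± 0.4, adjusted p = 0.00907). In the list of matrix crosslinking and proteolysis 3 of 34 rose (13 over the list alone; median 0.66, camera adjusted p = 1.0e-08; adjusted p = 0.275 with an estimated correlation). Among them were the lysyl oxidases Lox (1.77 ± 0.31, adjusted p = 0.0173) and Loxl1 (1.28 ± 0.22, adjusted p = 0.0155). Fibroblast and myofibroblast genes had a median of 0.74 with 3 of 29 called (7 over the list alone; camera, adjusted p = 3.8e-08; adjusted p = 0.275 with an estimated correlation). They included Pdgfrb, the pericyte growth-factor receptor (0.93 ± 0.2, adjusted p = 0.0461). Tgfb2 rose (1.76 ± 0.32, adjusted p = 0.0216) while Col3a1 (1.44 ± 0.46, adjusted p = 0.116) and Tgfb1 (1.1 ± 0.31, adjusted p = 0.0834) were not called. Both were called without the libraries labelled 14 days (1.43, adjusted p = 0.00109, and 1.09, adjusted p = 0.00589). Col1a1 (ENSRNOG00000003897) lies on chromosome 10 from 82745801 to 82762789.

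Genes of macrophages, lymphocytes and antigen presentation shifted upward together from 3 to 7 days. The medians were 1.14 for monocyte and macrophage genes (34 members, 3 rose, 25 over the list alone; camera, adjusted p = 1.0e-15) and 1.2 for T and NK cell genes (31 members, 0 called, 22 over the list alone; adjusted p = 3.1e-14). For MHC class II presentation it was 1.4 (14 members, 1 rose, 14 over the list alone; adjusted p = 1.3e-09), and each of the 3 lists had an adjusted p = 0.259 with an estimated correlation. Aif1, a macrophage cytoskeletal protein, rose by 1.55 ± 0.3 (edgeR, adjusted p = 0.0282), the pan-leukocyte tetraspanin Cd53 by 1.5 ± 0.28 (adjusted p = 0.0254). The class II gene RT1-Bb rose by 1.81 ± 0.41 (adjusted p = 0.0487) and the dendritic cell lectin Clec4a by 2.02 ± 0.38 (adjusted p = 0.0271). The T cell chemokine receptor Cxcr3 (1.57 ± 0.37, adjusted p = 0.0548) and perforin gene Prf1 (1.48 ± 0.36, adjusted p = 0.0549) were not called, but were so without the libraries labelled 14 days (1.55, adjusted p = 0.0243, and 1.47, adjusted p = 0.0229). Replicate 4 of day 7 contributed much of the lymphocyte signal, and without it the medians of T and NK cell and class II genes were 0.7 and 0.9. Neutrophil genes were not called as a list (10 members, median 0.29, camera adjusted p = 0.73).

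Fatty acid oxidation and tubule lists moved the other way, from day 3 scores above those of day 1. Mean scores at 1, 3 and 7 days were −0.15, 0.66 and 0.34 for proximal tubule genes. They were −0.16, 0.28 and 0.02 for loop and distal genes, and 0, 0.33 and −0.1 for fatty acid oxidation. For 7 versus 1 day without the libraries labelled 14 days, neither tubule list was called (camera, adjusted p = 0.2745 and 0.9086). Fatty acid oxidation was lower there (adjusted p = 0.032; 0.8774 with an estimated correlation). Of 41 fatty acid oxidation genes 2 fell and 0 rose (5 fell over the list alone), median −0.42 (camera, adjusted p = 1.1e-08; adjusted p = 0.498 with an estimated correlation). Cpt1a, the carnitine acyltransferase that admits fatty acids to mitochondria, went from 63.5 ± 12.8 to 34.2 ± 9.02 FPKM (−0.96 ± 0.22, edgeR adjusted p = 0.0488). In the list of TCA cycle and pyruvate oxidation 2 of 33 fell (3 over the list alone; median −0.24, camera adjusted p = 6.5e-05; adjusted p = 0.568 with an estimated correlation). They were Pdk4, the pyruvate dehydrogenase kinase induced by fasting, from 28.4 ± 15.4 to 4.22 ± 2.03 FPKM (−2.82 ± 0.46, adjusted p = 0.0117), and malic enzyme Me1 (−0.62 ± 0.12, adjusted p = 0.0303). Neither is an enzyme of the cycle itself, and none of those was called over all tested genes. Loop and distal tubule genes had a median of −0.32 with 0 of 22 called (camera, adjusted p = 0.0131; adjusted p = 0.571 with an estimated correlation). Proximal tubule genes (39 members, 0 called, median −0.46, camera adjusted p = 0.0209; adjusted p = 0.712 with an estimated correlation) lost their call without replicate 3 of day 3 (median −0.06, adjusted p = 0.399), replicate 1 of day 7 (−0.37, adjusted p = 0.0646) or replicate 4 of day 7 (−0.28, adjusted p = 0.128). Urothelium genes had a median of −3.83 with 0 of 11 called (camera, adjusted p = 0.0147; adjusted p = 0.61 with an estimated correlation). That call was lost without replicate 1 of day 3, whose urothelium score was 1.82 (median −1.58, adjusted p = 0.0952). Mitochondrially encoded genes (median −0.32, adjusted p = 0.0631) and cell cycle genes (median 0.1, adjusted p = 0.292) were not called.

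Among well-expressed genes, Il24, a cytokine of the IL-10 family, had a large rise from 3 to 7 days, from 6.85 ± 2.52 to 44.9 ± 16.0 FPKM (2.64 ± 0.35, adjusted p = 0.0042). Ccdc80, a secreted matrix protein, went from 21.03 ± 6.39 to 87.6 ± 28.1 FPKM (1.98 ± 0.26, adjusted p = 0.0042). Cthrc1, a collagen-triple-helix protein of activated fibroblasts, went from 1.69 ± 0.459 to 9.45 ± 4.62 (2.4 ± 0.38, adjusted p = 0.0116) and Cpz from 10.6 ± 4.06 to 37.1 ± 7.22 (1.73 ± 0.25, adjusted p = 0.0056). In all, 152 genes differed, 104 higher and 48 lower (edgeR, Benjamini-Hochberg; 2726 at an unadjusted p under 0.05). Without the libraries labelled 14 days the count was 1108 (664 higher, 444 lower, 150 shared). Havcr1 (−0.37 ± 0.53, adjusted p = 0.78) and Spp1 (0.04 ± 0.41, adjusted p = 0.976) were not called. The groups separated fully in 1205 genes (8.3%, 0.794% by chance). The split was 105 higher and 16 lower with log2(FPKM+1) and 43 and 6 with TPM. Il24 (ENSRNOG00000004470) lies on chromosome 13 from 47618452 to 47623849.

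Single libraries moved the 7 versus 3 day count widely. It was 65, 80, 73 and 72 without replicates 1 to 4 of day 1, and 15, 14, 62, 40 and 42 without replicates 1 to 5 of day 3. It was 29 and 16 without replicates 4 and 5 of day 7, and 870 and 356 without replicates 2 and 3 labelled 14 days. Il24, Ccdc80, Cthrc1, Cpz and Thbs2 kept their calls in every refit. Col1a1, Sparc, Lox, Loxl1, Pdgfrb, Tgfb2, Aif1, Cd53, RT1-Bb, Clec4a, Cpt1a, Pdk4 and Me1 lost theirs in at least 1, with fold changes that moved less than 1.5 times (for Col1a1 the highest adjusted p was 0.140, without replicate 2 of day 3). In all, 24 lists passed in this comparison, 17 higher and 7 lower, and none of them did with an estimated correlation.

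Because the libraries labelled 14 days differed so strongly from the rest, 7 days was also compared with 1 day, a comparison added after the data were seen. Over this interval 3713 genes differed, 1787 higher and 1926 lower (edgeR, Benjamini-Hochberg; 5468 at an unadjusted p under 0.05), and 5351 without the libraries labelled 14 days. With log2(FPKM+1) the split was 2044 higher and 1118 lower, and with TPM 1585 and 837. The 5 libraries of each group separated fully in 3082 genes (21.2%, 0.794% by chance).

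Most leukocyte lists rose from 1 to 7 days. In the monocyte and macrophage list 23 of 34 members rose (26 over the list alone; median 1.82, camera adjusted p = 7.1e-13) and in the T and NK cell list 26 of 31 (27; median 1.81, adjusted p = 7.5e-12). In MHC class II presentation it was 12 of 14 (13; median 2.14, adjusted p = 6.4e-10). No member of these lists fell, and each list had an adjusted p = 0.604 with an estimated correlation. Clec10a went from 1.77 ± 1.03 to 37.5 ± 27.1 FPKM (n = 5 each; 4.3 ± 0.6, edgeR adjusted p = 0.000251), and Trem2, a lipid-sensing receptor of macrophages, rose by 3.7 ± 0.58 (adjusted p = 0.000503). C1qa, of the complement C1q complex made by macrophages, went from 34.1 ± 10.4 to 161 ± 86.5 FPKM (2.16 ± 0.44, adjusted p = 0.00223). RT1-Da (3.69 ± 0.53, adjusted p = 0.000283) and Ciita (3.17 ± 0.54, adjusted p = 0.000797) rose. So did the T cell receptor subunit Cd3e (2.45 ± 0.45, adjusted p = 0.00119) and Cxcr3 (2.49 ± 0.39, adjusted p = 0.00052) and its ligand Cxcl9 (4.73 ± 1.02, adjusted p = 0.00333). B and plasma cell genes rose in 7 of 17 cases (8 over the list alone; median 1.18, camera adjusted p = 0.0114; adjusted p = 0.612 with an estimated correlation). That call was lost without replicate 4 of day 7 (median 0.56, adjusted p = 0.0744). Of 11 dendritic cell genes 5 rose and 1 fell (8 and 1; median 0.87, adjusted p = 0.00833; adjusted p = 0.612 with an estimated correlation). Neutrophil genes were not called as a list (10 members, 0 rose, 1 fell, median 0.39, adjusted p = 0.88).

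Matrix and mesenchymal genes rose over the same interval. Of 36 collagens and matrix proteins 19 rose and 0 fell (24 rose and 1 fell over the list alone; median 1.15, camera adjusted p = 1.7e-09; adjusted p = 0.604 with an estimated correlation). Of 29 fibroblast and myofibroblast genes 14 rose and 1 fell (15 and 2; median 1.21, adjusted p = 1.0e-06; adjusted p = 0.604 with an estimated correlation). Col1a1 went from 19 ± 4.46 to 90.5 ± 14.5 FPKM (2.17 ± 0.39, edgeR adjusted p = 0.00114). Mmp2, the gelatinase of stromal cells, went from 6.32 ± 1.74 to 35.9 ± 10.4 (2.43 ± 0.48, adjusted p = 0.00184) and Acta2, smooth muscle actin and the classical myofibroblast marker, from 36.9 ± 9.93 to 115 ± 22.7 (1.56 ± 0.36, adjusted p = 0.0056). Col3a1 (1.87 ± 0.47, adjusted p = 0.00833), elastin gene Eln (2.57 ± 0.48, adjusted p = 0.0014), Lox (2.18 ± 0.31, adjusted p = 0.000291) and the hedgehog effector Gli1 (2.21 ± 0.36, adjusted p = 0.000671) rose too. Tgfb1 rose by 0.97 ± 0.31 (adjusted p = 0.0299), and lost its call without any of replicates 1 to 4 of day 1 or 2, 4 and 5 of day 7 (adjusted p at most 0.0705).

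Cell cycle genes stayed above their day 1 level, with 29 of 46 members up and 0 down (31 over the list alone; median 1.29, camera adjusted p = 1.5e-22; adjusted p = 0.517 with an estimated correlation). Mki67 went from 1.47 ± 0.576 to 5.82 ± 1.19 FPKM (1.91 ± 0.27, edgeR adjusted p = 0.000251). The injured tubule list was mixed, with 4 of 28 up and 3 down (camera, adjusted p = 0.596). Havcr1 (−1.16 ± 0.53, adjusted p = 0.12) and Spp1 (0.64 ± 0.41, adjusted p = 0.279) were not called, but were so without the libraries labelled 14 days (−1.17, adjusted p = 0.00224, and 0.63, adjusted p = 0.0225). The falls included Sdcbp2 (−4.35 ± 0.64, adjusted p = 0.000331), Eef1a2 (−3.46 ± 0.4, adjusted p = 7.8e-05), Rsad2 (−3.12 ± 0.58, adjusted p = 0.00133) and Hpx (−2.98 ± 0.43, adjusted p = 0.000289). The 13 lists that passed all pointed up, and none of them did with an estimated correlation. Sox11, a transcription factor of the developing nephron, went from 35.3 ± 12.7 to 6.38 ± 0.493 FPKM (−2.55 ± 0.44, adjusted p = 0.000917).

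**Figure D2:**
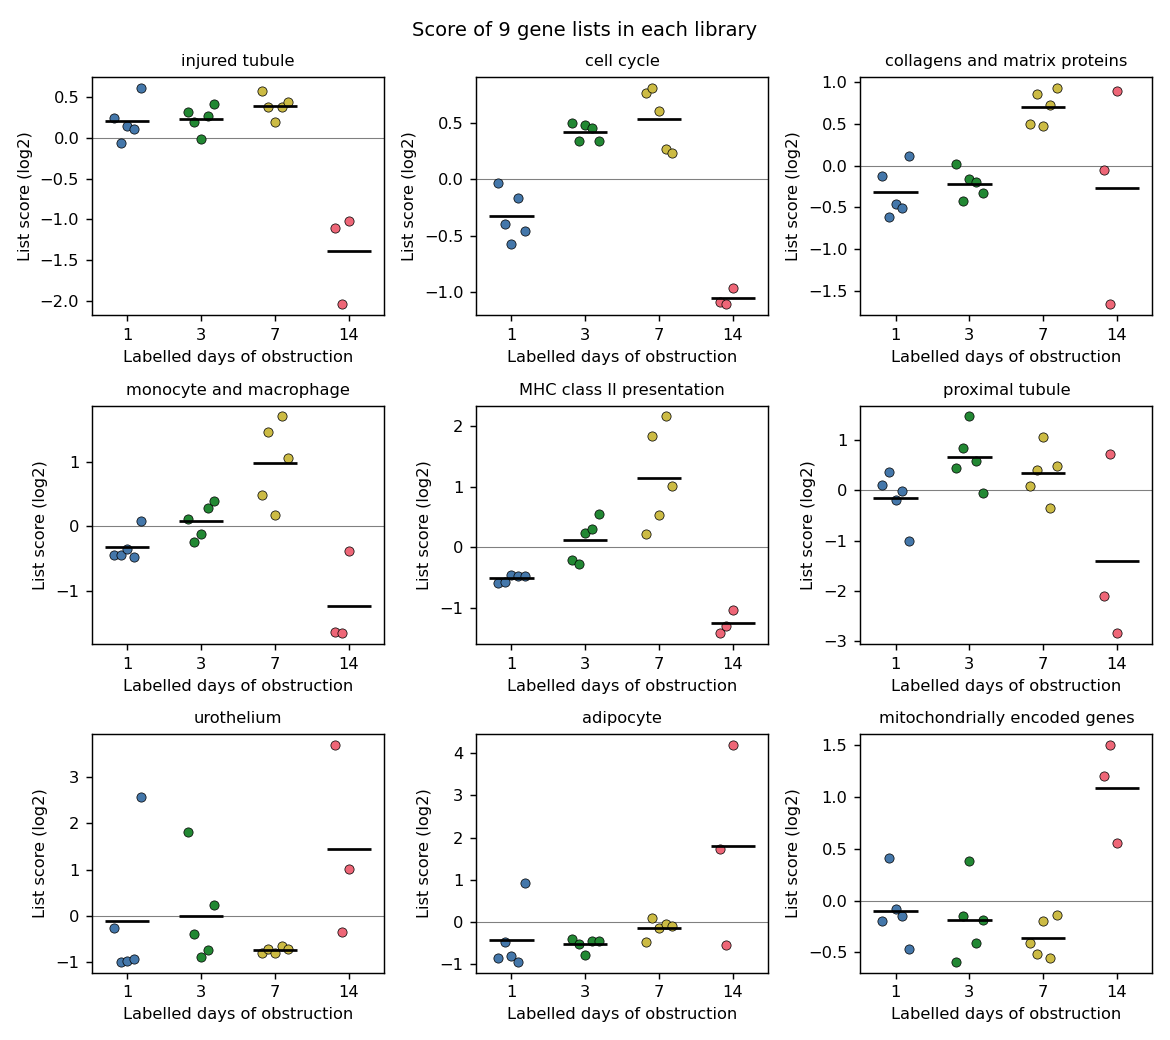
Scores of 9 gene lists in each library against the labelled days of obstruction. A score is the mean, over the tested members of a list, of log2(FPKM+1) centred on each gene's mean over the 18 libraries, with points for libraries and bars for group means.

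In the libraries labelled 14 days, tubular injury genes were far below their 7 day level. Of 28 injured tubule genes 13 fell and 0 rose (14 fell over the list alone), median −0.88 (camera, adjusted p = 2.5e-07; adjusted p = 0.0448 with an estimated correlation). Havcr1 was 85.9-fold lower, from 381 ± 91.6 (n = 5) to 3.10 ± 3.82 FPKM (n = 3; −6.42 ± 0.85, edgeR adjusted p = 6.4e-05). Spp1 was 62.8-fold lower, from 10960 ± 1611 to 125 ± 117 FPKM (−5.97 ± 0.65, adjusted p = 1.2e-05). Clu, the chaperone clusterin of damaged tubules, went from 3190 ± 712 to 114 ± 68.0 FPKM (−4.57 ± 0.4, adjusted p = 2.6e-06) and the iron-binding lipocalin Lcn2 from 283 ± 123 to 8.99 ± 4.52 (−4.72 ± 0.79, adjusted p = 0.000347). Each of the 3 libraries stood outside the other 15. Havcr1 was at 5.97, 29.2 and 1.24 CPM in replicates 1, 2 and 3 against 734 to 4072 elsewhere, and Clu at 301, 134 and 505 against 4273 to 11480. Clu (ENSRNOG00000016460) lies on chromosome 15 from 42640146 to 42665857.

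Genes of proliferation, macrophages, T and NK cells and class II presentation were also low in these libraries. In the cell cycle list 40 of 46 members fell and 0 rose (41 fell over the list alone; median −2.42, camera adjusted p = 2.8e-34; adjusted p = 0.0954 with an estimated correlation). Cdk1, the kinase that drives mitosis, was at 9.60 ± 2.32 and 0.271 ± 0.334 FPKM (−4.82 ± 0.53, edgeR adjusted p = 1.4e-05) and Mki67 at 5.82 ± 1.19 and 0.345 ± 0.172 (−3.76 ± 0.37, adjusted p = 6.0e-06). Of 34 monocyte and macrophage genes 28 fell (29 over the list alone; median −2.61, camera adjusted p = 3.1e-16; adjusted p = 0.28 with an estimated correlation). Of 31 T and NK cell genes 23 fell (24; median −2.54, adjusted p = 6.4e-10; adjusted p = 0.375 with an estimated correlation), and of 14 class II presentation genes 14 (median −3.42, adjusted p = 2.2e-09; adjusted p = 0.28 with an estimated correlation). No member of these 3 lists rose. Neutrophil genes were not called as a list (10 members, 2 rose, 3 fell, median −0.77, mean 0, adjusted p = 0.319). Cd74, the invariant chain of class II molecules, went from 1193 ± 885 to 46.8 ± 12.7 FPKM (−4.34 ± 0.61, adjusted p = 9.8e-05) and the lysozyme gene Lyz2 from 1660 ± 1220 to 99.6 ± 49.8 (−3.73 ± 0.58, adjusted p = 0.000222). Of 37 chemokine and cytokine genes 15 fell and 2 rose (15 and 3 over the list alone; median −0.83, camera adjusted p = 0.000128; adjusted p = 0.292 with an estimated correlation). That median was −0.55 without replicate 2 of day 7, and −1.39, −1.49 and −1.94 without replicates 1, 2 and 3 labelled 14 days. The list medians of T and NK cell and of chemokine and cytokine genes were the same with their members at 0 counts set to a bound. Its member Il19 changed by −5.23 ± 0.65 (adjusted p = 3.8e-05) and Il24, outside the list, by −7.24 ± 0.65 (adjusted p = 3.3e-06). The IL-6 family gene Lif changed by −5.17 ± 0.48 (adjusted p = 3.7e-06; 22.6 ± 7.74 to 0.497 ± 0.261 FPKM) and complement C3 by −5.16 ± 0.93 (adjusted p = 0.000633; 46.7 ± 27.1 to 1.01 ± 0.421 FPKM). Cd74 (ENSRNOG00000018735) lies on chromosome 18 from 56071478 to 56080849.

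Matrix genes were mixed between the libraries labelled 14 days and those at 7 days. Of 36 collagens and matrix proteins 14 fell and 4 rose (15 and 4 over the list alone; median −0.84, camera adjusted p = 0.00143; adjusted p = 0.694 with an estimated correlation). Col1a1 went from 90.5 ± 14.5 to 13.0 ± 12.3 FPKM (−2.63 ± 0.49, edgeR adjusted p = 0.000764) and Loxl1 from 106 ± 26.2 to 10.1 ± 4.02 (−3.11 ± 0.29, adjusted p = 3.7e-06). Adamts1, a versican-cleaving protease, went from 328 ± 56.4 to 12.6 ± 2.91 (−4.34 ± 0.37, adjusted p = 2.2e-06), whereas the proteoglycan gene Vcan rose (4.72 ± 0.87, adjusted p = 0.000739). The collagen call was lost without replicate 2 labelled 14 days (median −0.48, adjusted p = 0.347) and its median was −1.3 without replicate 3. Fibroblast and myofibroblast genes split evenly, with 8 of 29 up and 8 down (median 0.29, although the test pointed down, camera adjusted p = 0.554).

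Among 39 proximal tubule genes 11 fell and 3 rose (11 and 3 over the list alone), with a median of 0.22, a mean of −0.35 and a test that pointed down (camera, adjusted p = 0.00143; adjusted p = 0.731 with an estimated correlation). On the TPM scale the median was −1.95. Slc5a2, the glucose transporter SGLT2 of the early proximal tubule, went from 151 ± 43.4 to 4.61 ± 1.47 FPKM (−4.66 ± 0.57, edgeR adjusted p = 3.2e-05). The sodium-coupled lactate transporter Slc5a12 went from 21.4 ± 5.76 to 0.541 ± 0.288 (−4.98 ± 0.61, adjusted p = 3.2e-05). Neither loop genes (22 members, 8 rose, 3 fell, median 0.76, camera adjusted p = 0.382) nor principal cell genes (18 members, 9 rose, 1 fell, median 0.87, adjusted p = 0.111) were called as lists. The loop gene Umod (3.41 ± 1.05, adjusted p = 0.0174) rose only through replicate 2, without which it was at −1.02 (adjusted p = 0.277). The distal gene Egf (3.69 ± 0.81, adjusted p = 0.00241) rose mostly through replicate 2, without which it was at 0.96 and not called (adjusted p = 0.169). Egf was at 58.72, 492.4 and 12.1 CPM in replicates 1 to 3, against 12.37 to 46.16 at 7 days. Aqp2, the vasopressin-regulated water channel, rose from 27.5 ± 12.7 to 505 ± 401 FPKM (4.39 ± 0.86, adjusted p = 0.00113), with 2608, 165 and 2920 CPM in replicates 1 to 3. The proximal median was 0.75, −3.23 and 0.77 without replicates 1, 2 and 3 in turn (adjusted p = 0.11 without replicate 3), and 0.48 and 0.03 without replicates 3 and 4 of day 7. Slc5a2 (ENSRNOG00000020039) lies on chromosome 1 from 199682688 to 199688809.

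Markers of neighbouring tissues and of mitochondria were high in the same libraries. Of 11 urothelium genes 11 rose (median 6.68, camera adjusted p = 0.0173; adjusted p = 0.694 with an estimated correlation). The scores were 3.7, −0.36 and 1.01 in replicates 1 to 3, and the median was 3.26 (adjusted p = 0.0429) without replicate 1. Of 13 adipocyte genes 11 rose (12 over the list alone; median 3.42, adjusted p = 0.00838; adjusted p = 0.505 with an estimated correlation). The scores were 1.74, −0.55 and 4.19, and the call was lost without replicate 3 (median 2.34, adjusted p = 0.074). Plin1, the lipid-droplet coat of fat cells, was at 0.192 ± 0.361 and 53.5 ± 77.1 FPKM (8.25 ± 1.79, edgeR adjusted p = 0.00225). Of 21 endothelial genes 11 rose (14 over the list alone; median 1.2, camera adjusted p = 0.000339; adjusted p = 0.603 with an estimated correlation; 0.62 without replicate 3). Among them was Vwf, the von Willebrand factor gene (2.4 ± 0.5, adjusted p = 0.00159). With replicate 2 as the only library labelled 14 days, the medians were 3.04 for urothelium, −0.94 for adipocyte and −0.09 for endothelial genes, without a p since 1 library has no spread of its own. Of 11 mitochondrially encoded genes 11 rose (median 1.89, camera adjusted p = 4.1e-09; adjusted p = 0.28 with an estimated correlation). Mt-nd4l, which overlaps its neighbour and so shares reads with it, rose by 2.18 ± 0.29 (adjusted p = 6.5e-05).

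In all, 5560 genes differed between the libraries labelled 14 days and those at 7 days, 3102 higher and 2458 lower (edgeR, Benjamini-Hochberg; 6834 at an unadjusted p under 0.05). Of the lists 19 passed, 5 higher and 14 lower. The strongest single call was Me1, a source of NADPH for lipid synthesis, which went from 16.5 ± 2.18 to 74.0 ± 27.0 FPKM (2.43 ± 0.14, adjusted p = 7.5e-08). The proto-oncogene Myc went from 77.1 ± 12.6 to 8.84 ± 3.01 FPKM (−2.77 ± 0.24, adjusted p = 2.7e-06). The balance of higher and lower genes depends on scaling, with 906 higher and 4855 lower for log2(FPKM+1), 536 and 5850 for TPM and 2138 and 2915 for upper-quartile factors. The median shifts over all genes were −0.34, −0.5 and −0.11 in that order. The libraries of both groups separated fully in 4285 genes (29.5%, 3.57% by chance). Me1 (ENSRNOG00000009715) lies on chromosome 8 from 94256839 to 94368834.

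Against 1 day of obstruction the libraries labelled 14 days again had lower levels of injury transcripts. Of 28 injured tubule genes 11 fell and 0 rose (11 fell and 2 rose over the list alone; median −0.58, camera adjusted p = 1.5e-06; adjusted p = 0.0513 with an estimated correlation). Havcr1 was 192-fold lower, from 801 ± 160 to 3.10 ± 3.82 FPKM (−7.59 ± 0.9, edgeR adjusted p = 3.1e-05). Clu went from 1898 ± 321 to 114 ± 68.0 (−3.91 ± 0.39, adjusted p = 7.5e-06). Apcs, the serum amyloid P component, went from 70.5 ± 25.3 to 0.611 ± 0.565 FPKM (−6.6 ± 0.62, adjusted p = 4.9e-06). C3 changed by −6.37 ± 0.99 (adjusted p = 0.000266) and the fibrinogen chain Fgg by −5.82 ± 0.78 (adjusted p = 9.1e-05). The complement and coagulation list was not called (38 members, 8 fell, 3 rose, median 0.11 although the test pointed down, camera adjusted p = 0.0807). Of the lists 11 passed, 4 higher and 7 lower. Sox11 (−6.7 ± 0.77, adjusted p = 2.6e-05) and Mab21l3 (−6.49 ± 0.43, adjusted p = 6.5e-07; 103 ± 22.1 to 0.940 ± 0.374 FPKM) were among the largest falls.

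In the cell cycle list 27 of 46 members fell and 2 rose (31 and 2 over the list alone; median −1.21, camera adjusted p = 3.4e-10; adjusted p = 0.708 with an estimated correlation). Mki67 changed by −1.86 ± 0.35 (edgeR, adjusted p = 0.00121). Of 34 monocyte and macrophage genes 11 fell and 0 rose (11 over the list alone; median −0.8, camera adjusted p = 0.000579; adjusted p = 0.928 with an estimated correlation). The median was −0.48 and −1.55 without replicates 1 and 3 labelled 14 days. The fractalkine receptor gene Cx3cr1 changed by −2.41 ± 0.48 (adjusted p = 0.00157). Immediate early genes fell in 8 of 28 cases and rose in 5 (11 and 5 over the list alone; median −0.46, camera adjusted p = 0.0114; adjusted p = 0.708 with an estimated correlation). That call was lost without replicate 5 of day 1 (adjusted p = 0.0538). Among them Fosl1 changed by −3.2 ± 0.52 (adjusted p = 0.000365) and Myc by −2.8 ± 0.24 (adjusted p = 2.6e-06), from 74.3 ± 8.62 to 8.84 ± 3.01 FPKM.

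Lists of stromal and vascular genes were higher than at 1 day. Of 29 fibroblast and myofibroblast genes 15 rose and 3 fell (16 and 3 over the list alone; median 1.07, camera adjusted p = 0.0027; adjusted p = 0.928 with an estimated correlation), the median being 1.79 without replicate 2. Myh11, smooth muscle myosin, went from 8.96 ± 3.28 to 85.6 ± 66.1 FPKM (3.38 ± 0.48, edgeR adjusted p = 0.000135). Acta2 went from 36.9 ± 9.93 to 199 ± 132 (2.56 ± 0.41, adjusted p = 0.000317), while Col1a1 was not called (−0.46 ± 0.44, adjusted p = 0.45). Endothelial genes rose in 14 of 21 cases (17 over the list alone; median 1.34, camera adjusted p = 5.1e-06; adjusted p = 0.708 with an estimated correlation), with 0.8 as the median without replicate 3. Beside these, 11 of 13 adipocyte genes rose (12 over the list alone; median 4.33, adjusted p = 0.00232; adjusted p = 0.708 with an estimated correlation; 2.24 without replicate 3). So did 11 of 11 mitochondrially encoded genes (median 1.44, adjusted p = 1.2e-06; adjusted p = 0.708 with an estimated correlation). With replicate 2 as the only library labelled 14 days the medians were −0.42 for fibroblast and myofibroblast, −0.16 for endothelial and −2.18 for adipocyte genes. Acta2 (ENSRNOG00000058039) lies on chromosome 1 from 252537615 to 252550394.

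Among transporters, Slc4a4, the basolateral bicarbonate carrier of the early proximal tubule, went from 58.4 ± 23.2 to 1.06 ± 0.239 FPKM (−5.52 ± 0.61, adjusted p = 2.1e-05). Slc25a48, a mitochondrial carrier, rose from 1.65 ± 0.494 to 43.2 ± 15.6 FPKM (4.87 ± 0.43, adjusted p = 3.0e-06) and Ranbp3l from 2.34 ± 1.49 to 125 ± 90.7 (5.88 ± 0.54, adjusted p = 4.3e-06). The aspartate and glutamate transporter Slc7a13 of the late proximal tubule rose by 7.86 ± 1.6 (adjusted p = 0.00187) through replicate 2 alone, with 19.6, 3612 and 23.6 CPM in replicates 1 to 3 (1.58, adjusted p = 0.221, without it). Over the whole proximal list 10 members fell and 6 rose (11 and 9 over the list alone), with a median of 0.81 and a mean of 0.14 although the test pointed down (camera, adjusted p = 0.0164; adjusted p = 0.928 with an estimated correlation). With log2(FPKM+1) the median was −1.19. That call was lost without replicate 1 (adjusted p = 0.279) or 3 (adjusted p = 0.508), and the median was −2.57 without replicate 2. In all, 4646 genes differed, 2570 higher and 2076 lower (edgeR, Benjamini-Hochberg; 6274 at an unadjusted p under 0.05). The libraries separated fully in 3420 genes (23.6%, 3.57% by chance). The split was 888 higher and 3618 lower with log2(FPKM+1), 543 and 4763 with TPM. It was 1769 and 2333 with upper-quartile factors and 1822 and 2296 with quantile scaling. The median shifts over all genes were −0.25 and −0.42 for the FPKM and TPM scales.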

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

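The tests of explanations in this part were all chosen after the results had been seen. The search for outlying libraries and the other splits of the libraries were fixed beforehand, except the splits for 7 versus 1 day. In groups of 5 libraries, 23 of 189 list scores and marker genes had an outlying library (gap to the nearest library above 0.71 of the group's range), where chance gives about 1 in 20, or 9.4. At day 1 there were 16, of which 14 were replicate 5, against 4 at day 3 and 3 at day 7. Outside replicate 5 of day 1 the flags were thus about as many as chance gives. The lists and genes do not vary independently, so the chance figure is only a guide.

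Replicate 5 of day 1 was the high library for the scores of principal cell (gap 0.821 of the range), endothelium (0.782), Wnt, Notch and Hedgehog (0.721), macrophage (0.768), neutrophil (0.731), chemokine (0.765), interferon (0.797), urothelium (0.796) and adipocyte genes (0.753). The same library was high for Cd68 (0.721; 28.7 FPKM against 13.9 to 17.1) and Aqp2 (0.737; 371 FPKM against 24.8 to 51.1). It was low for the tryptophan list (0.719), Lrp2 (0.744; 42.4 FPKM against 83.6 to 105) and Umod (0.783; 16.6 FPKM against 55.7 to 77.4). Replicate 2 of day 1 was high for intercalated cell (0.83) and glutathione genes (0.773). At day 3, Havcr1 was low in replicate 3 (0.962; 188 FPKM against 536 to 559), Lrp2 in replicate 5 (0.713; 53.5 FPKM against 119 to 164) and dendritic cell genes in replicate 2 (0.719), and the tryptophan list was high in replicate 3 (0.821). At day 7, replicate 4 was high for T and NK cell genes (0.764), Cd79a (0.747; 10.2 FPKM against 1.29 to 2.42) and Egf (0.763; 9.13 FPKM against 2.45 to 3.45).

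The markers of collecting duct, urothelium and fat that were high in replicate 5 of day 1 may reflect inner medulla or pelvis tissue in the piece sampled. If so, proximal tubule genes would be lowest there, and 82.1% of them (32 of 39) were, against 20% if each gene varied independently. Genes of a tissue do not vary independently, and low Lrp2 in this library had already been flagged. The count therefore describes the library and is no separate support. A library like those labelled 14 days under a day 1 label is argued against, since Havcr1, Spp1 and Clu in this library were 85.9, 23.1 and 9.47 times the highest library labelled 14 days (9.473 for the smallest). That ratio was chosen after an earlier test, in which 11 of 15 values (73.3%) lay nearer to the other day 1 libraries, had been seen and had not decided. It takes the 14 day labels as given, so it cannot decide on a kidney of 14 days if those labels are wrong. The design gives no biological explanation for this library and none was tested.

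Injury markers were low in each of the libraries labelled 14 days, with 13 of the 28 injured tubule genes lower and 0 higher than at 7 days. Few proximal tubule cells in the tissue are argued against as the whole cause of low Havcr1. The highest ratio of Havcr1 to the proximal gene Lrp2 in these libraries was 0.0563, against a lowest of 0.2895 in the other 15. Lrp2 itself was at 106, 2958 and 45.15 CPM in replicates 1, 2 and 3 (618.9 to 2536 elsewhere). Few proximal cells in replicates 1 and 3 therefore stay possible. The ratio does not bear on Spp1, Clu or Lcn2. A larger share of mitochondrial transcripts accounts for only a small part of the fall. Taking counts per total outside the mitochondrial genome raises the log2 change of any other gene by 0.24, before the offset added for logs. That size is set by the mitochondrial shares alone. The median of the 13 genes, which were picked as lower in this same comparison, went from −2.3 per total count to −2.08. As 0 of the other 15 libraries had Havcr1, Spp1 and Clu all as low, these libraries resembled no other analysed group in these markers. That count restates the pattern itself, so it is no separate test of labels exchanged with another analysed group. Tissue from a kidney without obstruction could give the same picture (13 lower, 0 higher) and cannot be told apart, because no unobstructed library was analysed here, and a true effect of the longer duration stays open and untested.

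The counts of genes were each set against other splits of the same libraries into groups of the same sizes, with the real split counted among them. Except for 14 versus 1 day, no other split tried gave as many genes. The real split gave 6929 genes among the 4 durations (1 of 60 splits as large, highest other 156), 330 for 3 versus 1 day (1 of 100, highest other 4) and 152 for 7 versus 3 days (1 of 100, highest other 1). It gave 5560 for 14 versus 7 days (1 of 56, highest other 2303) and 3713 for 7 versus 1 day (1 of 100, highest other 477). For 14 versus 1 day it gave 4646, and 2 of 56 splits were as large, the highest other with 5252. That other split set replicate 5 of day 1 and replicates 1 and 3 labelled 14 days against the rest, which points to a structure of the samples. For 14 versus 1 day the real split was not the largest, so its count does not exceed what regrouping gives.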

How the results depend on the processing

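The settings that leave out the libraries labelled 14 days, replicate 5 of day 1 or mitochondrial genes, that keep only replicate 2 of those labelled 14 days, or that add a covariate were chosen after the results had been seen, as was the comparison of 7 with 1 day. The 330 genes of 3 versus 1 day became 218, 180 and 156 with limma on log2 FPKM (pseudocounts 1, 0.1 and 0.01), 166 with TPM, 171 with no filter and 153 with a size threshold of 1 on the log2 scale. More were called by DESeq2 (951), with the 2 groups alone (1203) and with array weights (2677). Without the libraries labelled 14 days there were 1463, and 2016 also without replicate 5 of day 1. With only replicate 2 of those labelled 14 days there were 1372, and 1936 also without replicate 5 of day 1, and with the covariate 867. Leaving out each library in turn gave 115 to 1159.

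The 152 genes of 7 versus 3 days became 32 and 18 with pseudocounts 0.1 and 0.01, 49 with TPM, 262 and 269 with median and quantile scaling, 64 with no filter and 94 with the size threshold. DESeq2 gave 909, the 2 groups alone 981, array weights 1473 and mitochondrial genes left out 100. Without the libraries labelled 14 days there were 1108 (1772 also without replicate 5 of day 1). With only replicate 2 of them there were 1067 (1771 also without replicate 5 of day 1), and with the covariate 942. Leaving out each library gave 14 to 870.

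Among the 4 durations the 6929 genes became 3381 with the size threshold and 11399 with array weights (5936 to 9317 with each library left out). For 14 versus 7 days, the size threshold gave 2858, the 2 groups alone 3153 and array weights 8904 (4559 to 7459). For 14 versus 1 day these gave 2365, 1628 and 8631 (3682 to 6405). For 7 versus 1 day the size threshold gave 1446, TPM 2422 and array weights 6582 (2834 to 5146). Without replicate 5 of day 1 it was 5841 with the libraries labelled 14 days left out and 5946 with only their replicate 2. The biological coefficient of variation was 0.3233 with and 0.2327 without the libraries labelled 14 days.

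Of the list tests 66 passed in the 4 planned comparisons, 58 to 85 with other settings, 38 with fry and 2 with an estimated correlation. Some values changed direction, and the cause was not tested. Where replicate 2 alone stands for the libraries labelled 14 days, the spread comes from the other groups. Umod for 14 versus 7 days was −0.5 with array weights and −1.02 without replicate 2 labelled 14 days, and for 14 versus 1 day −0.1 without it. Without replicate 3 they were 3.96 and 4.89. With only replicate 2 labelled 14 days, Plin1 was −5.44 (14 versus 7 days) and −8.27 (14 versus 1 day), or −5.4 and −3.16 also without replicate 5 of day 1. The proximal tubule list then pointed up, with medians 1.74 and 2.03, or 1.74 and 1.86 also without replicate 5 of day 1, and 0.86 with the covariate for 14 versus 1 day. The fibroblast list of 14 versus 1 day pointed down, with medians −0.42 and 0.07. Over all settings, values of named genes stayed on the same side of the threshold in 7215 cases, lost the call in 577 and gained it in 107, and changed direction in the 7 given here. For lists, 2765 stayed, 321 lost the call and the 7 given here changed direction.

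With the replicate number as a block, 139 genes were called for 3 versus 1 day (136 of them shared) and 39 for 7 versus 3 days (36 shared). The other counts stayed within 1.5 times, at 5709 among the 4 durations, 4485 for 14 versus 7 days, 3985 for 14 versus 1 day and 3363 for 7 versus 1 day. No clear pairing by number was seen, but its absence cannot be concluded. Of 24 same-number pairs 10 deviated together by more than 0.1 (range −0.424 to 0.395), with no summary of different-number pairs as a reference. Only 2 of 18 libraries had their best match, among the libraries of other groups, with their own number.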

Other observations

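The comparison of 7 with 1 day and the test of sampled tissue in this part were chosen only after the results had been seen. Of 37 chemokine and cytokine genes 12 rose and 3 fell between 1 and 7 days (13 and 3 over the list alone; median 0.55, camera adjusted p = 0.0169; adjusted p = 0.612 with an estimated correlation). The median was 0.87 without replicate 5 of day 1, and the call was lost without replicate 4 of day 7 (adjusted p = 0.0535). Il33, an alarmin released by damaged cells, went from 285 ± 103 to 88.14 ± 19.97 FPKM (n = 5 each; −1.77 ± 0.44, edgeR adjusted p = 0.00822). Cxcl11, a ligand of CXCR3, went from 66.7 ± 18.4 to 18.3 ± 13.2 FPKM (−1.95 ± 0.52, edgeR adjusted p = 0.0124), whereas Cxcl9, a second ligand of that receptor, rose (4.73 ± 1.02, edgeR adjusted p = 0.00333). Fgb, the fibrinogen beta chain, went from 61.1 ± 30.8 to 12.5 ± 3.72 FPKM (−2.39 ± 0.62, edgeR adjusted p = 0.0103). The Wnt ligand gene Wnt2 changed by −2.85 ± 0.41 (edgeR adjusted p = 0.000373) and the Wnt antagonist gene Sfrp1 by 2.12 ± 0.27 (edgeR adjusted p = 0.000141).

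Transporter genes of single nephron segments differed sharply between the 3 libraries labelled 14 days, here in CPM for replicates 1, 2 and 3 with the range of the other 15 libraries. The inner medullary urea transporter Slc14a2 was at 484, 0 and 358 (0 to 80.2), the aldose reductase gene Akr1b1 at 3934, 12.3 and 3563 (26.3 to 124) and Aqp3 at 816, 70.2 and 836 (15.4 to 682). The late proximal gene Slc3a1 was at 47.3, 4001 and 30.3 (381 to 1445) and the thick limb genes Umod and Slc12a1 at 151, 5041 and 60.5 (36.8 to 845) and at 72.2, 1701 and 32.1 (143 to 1283). The distal tubule gene Slc12a3 was at 424, 335 and 6.98 (205 to 687.5) and the podocyte gene Nphs1 at 38.3, 38.6 and 0.776 (26.5 to 110.5). Replicate 5 of day 1 held 1393 CPM of Aqp2 and 80.2 of Slc14a2.

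The 5 early proximal transporter genes examined were low in each of these 3 libraries. Slc5a2 was at 11.6, 19.2 and 11.3 CPM (102 to 702) and Slc7a7 at 10.8, 4.62 and 29.2 (147 to 406.5). The proximal phosphate transporter gene Slc34a1, not among the 5, was at 138.6, 1479 and 20.64 CPM (69.42 to 2954). It was thus inside the range of the other 15 libraries in replicates 1 and 2. Medulla sampled in place of cortex would lower the other cortical markers equally. For replicates 1 and 2 that is argued against as the whole cause of the low levels of these 5 genes. Medulla as a part of these pieces is not argued against. Inner medulla markers had a median log2 change of 5.24 in replicate 1 and 5.25 in replicate 3, from the mean of the other 15 libraries. In replicate 2 late proximal (3.26) and thick limb markers (2.23) were high instead. The 5 early proximal markers lay below 9 glomerular and distal convoluted markers by 3.58 and 4.02 on the log2 scale in replicates 1 and 2, beyond the range of −1.05 to 1.17 in the other 15 libraries. They include Slc5a2, Slc5a12 and Slc4a4, which had already been seen to be low in these libraries. The size of the gap is therefore in part set by the choice of markers. It does not bear on other early proximal genes. In replicate 3 the gap was 1.06, inside that range, so medulla in that piece stays possible. A loss of these early proximal transporters with duration is a candidate explanation for replicates 1 and 2 that was not tested. Tissue from outside the study's obstructed kidneys is another, also untested.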
